A study of Homo sapiens with 9 samples.

How the data were processed

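RNA sequencing of total RNA was deposited for 9 libraries of Caki-1, a human line derived from a clear cell renal carcinoma. Per the labels, 3 libraries are controls (genotype WT) and 6 carry a knockdown of TAF1D by short hairpin RNA, 3 named SH1 and 3 named SH3. The labels do not say what SH1 and SH3 stand for. Each library was assigned to its group by its own label, with 0 columns of the deposited table left unassigned. The labels number the libraries 1 to 3 in each group but do not say whether they come from separate cultures. The p-values therefore measure the spread between these samples alone, which may be technical.

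The deposited table holds 20909 transcripts of 6819 genes. Of these transcripts, 10958 have curated RefSeq names, 9036 have predicted RefSeq names, and 915 are further copies of a transcript placed elsewhere in the annotation. Per the file headers, 4 columns are given per library. The deposited estimated count (an expected count, 65.11% of the values not whole) was rounded and used for the tests. The deposited FPKM was used to describe levels. The deposited TPM was used for the share of a library that the listed transcripts cover. The deposited normalized read count, a signal on a linear scale, equals the estimated count rounded up and divided by 1 factor per library in 100% of the values (relative tolerance 1e-06). The authors' processing notes name the mouse build mm10 and no tool, whereas 20900 transcripts (99.957%) carry gene numbers found in the human RefSeq table (assembly GRCh38.p14). The values were therefore read as human. Symbols of 85 genes were updated by gene number, and no positions are given.

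The table is a selection. All 20909 transcripts differ by at least 2-fold between control 1 and SH1 1 (10960 higher and 9949 lower in SH1 1), against 51.51% to 64.85% in the other 35 pairs of libraries. Values of these 2 libraries are therefore more extreme than those of the other 7, and genes outside the table were not analysed here, TAF1D among them. The knockdown was not checked on its target. The edgeR counts of transcripts and of sums, and the lists on both, were also computed without control 1 and SH1 1, a choice made after seeing the data; these values are called "the other 7 libraries".

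Estimated counts of the listed transcripts add up to 1358215 to 1596467 per library. They are part of a library, 4.202% to 5.176% of all TPM, and not its depth. In each library 11422 to 13944 transcripts had a count of at least 10, where counting error alone is 31.6% or less. Between 3417 and 3882 had at least 100 (10% or less) and 111 to 153 at least 1000 (3.16% or less). A count of 0 in all libraries of a group was replaced by 3 counts over the group to give a bound on the fold. Bounds and these errors cover counting error only.

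Differential expression was tested on deposited transcripts with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3). TMM scaling, the default filterByExpr (minimum count 10) and robust dispersions were used, in 1 fit of all 9 libraries with a mean per group. The comparisons were SH1 and SH3 each against control, their average against control, and SH3 against SH1. After the filter 17495 transcripts of 6351 genes remained. The p-values were adjusted by Benjamini-Hochberg in each comparison with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size over the square root of the quasi-likelihood F. The comparisons, tests, threshold, gene lists, rule for named genes and the first group of alternatives were set before the data were examined.

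Of 40 gene lists (934 members in all) 31 had at least 5 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), adjusted by Benjamini-Hochberg over the lists. A gene entered with its listed transcript of the higher mean. Estimated correlation, fry and ranks were alternatives. The remaining 9 lists had too few measured members: 0 each for genes of the mitochondrial genome, small nucleolar RNAs in TAF1D introns and hosts of small nucleolar RNAs, 4 each for histones and clear cell carcinoma markers, 3 for renal tubule genes, 1 for endothelial, 2 for fibroblast and 2 for blood cell markers.

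The rule for named genes took 19 genes in any case, of which 11 were tested. It added transcripts past the threshold with a mean of at least 1 FPKM and no overlap between groups: up to 10 each way for changes shared by SH1 and SH3, up to 5 each way per comparison, and up to 4 members of a described list. The other transcripts past the threshold are named because the counts were small; they, and the 12 genes of the FPKM plot, were chosen after their values were seen.

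The first group of alternatives was DESeq2 size factors, no TMM, no filter, a stricter filter (mean of 5 CPM), the DESeq2 Wald test (DESeq2 1.42.0), limma-trend on log2 of FPKM plus 1, a fit of only the groups compared, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library. Chosen after seeing the data were the other 7 libraries, sums of the listed transcripts of a gene, both together, genes with 1 annotated transcript, the authors' factors, totals from count over FPKM, edgeR without robust dispersions, and DESeq2 and limma-voom on sums. The sums were set beside the transcripts after counts of calls by both had been seen; transcripts stayed the tested unit.

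The test was tried on simulated data with groups of 3 at the measured means. With dispersions shrunken towards the trend, 0 of 67 transcripts changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 8-fold were recovered in each comparison (13663 to 13758 tested). The direction of the 8-fold changes was right in 65.2% to 80.3%. With each transcript's own dispersion, a choice made after those results were seen, 0 (SH1 against control) to 6 (averaged) of 66 changed 8-fold were recovered (16156 to 16267 tested), with 86.4% to 95.5% in the right direction. In both kinds 0 unchanged transcripts were called. In these simulations the transcript test therefore missed most changes of these sizes. For sums, 14 to 27 of 66 changed 8-fold were recovered with shrunken and 34 to 42 with own dispersions; 0 unchanged sums were called with the former and 1 to 4 with the latter. In the list test a list shifted 4-fold in SH1 was found in 20 of 20 simulations, and 0 of 539 other lists were called.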

Results

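RNA of Caki-1 cells was sequenced in 9 libraries, 3 of control cells and 3 of each of the knockdown groups SH1 and SH3. TAF1D, the targeted gene, encodes a subunit of SL1, the factor that brings RNA polymerase I to the promoters of ribosomal RNA genes. The study asks about its role in clear cell renal carcinoma and names PI3K, AKT and mTOR signalling. The estimated counts of the listed transcripts added up to 1412867, 1358215 and 1406799 in controls 1 to 3. They were 1529677, 1520518 and 1596467 in SH1 and 1450201, 1461367 and 1466297 in SH3. Levels below are mean FPKM ± SD and fold changes are log2 ± SE, with n = 3 libraries per group. All listed transcripts had been selected on a difference between control 1 and SH1 1, and TAF1D was not analysed here.

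The comparison of SH1 with control asks what the knockdown changes, and single genes moved both ways. C3, the central component of complement (NM_000064), rose from 11.7 ± 2.29 to 90.3 ± 15 FPKM (2.84 ± 0.19, adjusted p = 0.00101). CSF3, the granulocyte growth factor (NM_172219), rose from 67.9 ± 8.15 to 220 ± 14.4 (1.58 ± 0.13, adjusted p = 0.00248), and the chemokine CXCL1 from 198 ± 13.3 to 410 ± 22.6 (0.94 ± 0.10, adjusted p = 0.00634). IGFBP3, which binds insulin-like growth factors (NM_000598), fell from 28 ± 2.69 to 2.56 ± 0.24 (-3.56 ± 0.29, adjusted p = 0.00234). ADAMTS1, a secreted metalloproteinase (NM_006988), fell from 43.8 ± 1.15 to 9.17 ± 0.247 (-2.37 ± 0.15, adjusted p = 0.000832).

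Further genes with higher transcripts in SH1 were GOLGA7B (NM_001010917), from 0.177 ± 0.0306 to 8.62 ± 1.88 FPKM, and the adhesion molecule L1CAM, with both of its listed transcripts (log2 fold changes 2.11 ± 0.20 and 2.94 ± 0.26). The membrane repair protein gene MYOF (2.83 ± 0.33), the transcription factor gene EGR1 (2.0 ± 0.21) and STMN3, a member of the stathmin family (1.04 ± 0.15), rose as well. Keratin 19 (KRT19) fell from 80.7 ± 9.81 to 18.2 ± 3.15 FPKM (-2.26 ± 0.23). The matrix genes VCAN (-1.32 ± 0.17) and FBN1 (-1.25 ± 0.19) fell, as did the actin-binding PFN2 (-1.56 ± 0.16), UBASH3B (-1.48 ± 0.19), the O-fucosyltransferase POFUT1 (-1.11 ± 0.12) and the ribosomal protein gene RPS24 (-1.36 ± 0.18). Adjusted p of these transcripts lay between 0.00282 (GOLGA7B) and 0.0489 (FBN1).

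The remaining 6 changed transcripts had 0 counts in every library of 1 group. In SH1 a transcript of SYNCRIP was at least 506-fold higher (adjusted p = 0.00282), one of UBR4 at least 271-fold (0.036), one of TNFAIP3 at least 262-fold (0.0216) and one of WSB1 at least 184-fold (0.0216). One of GPR176 was at least 717-fold lower (0.0216) and one of LRRC8A at least 501-fold lower (0.0129). These genes have between 2 (TNFAIP3) and 13 (UBR4) listed transcripts, and the sum of the listed transcripts passed the threshold in 0 of these 6 genes in the edgeR test.

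In all, 24 transcripts of 23 genes differed between SH1 and control in the edgeR quasi-likelihood test, 13 higher and 11 lower, of 17495 tested. In 24 of 24 the libraries of the groups did not overlap. Chance gives that for 10% of transcripts not chosen by their p, a share that ignores the selection on control 1 and SH1 1. For called transcripts it is no separate test. At an unadjusted p under 0.05 there were 1367, against 875 at a share of 0.05, which ignores the selection of the table. Simulated unchanged groups selected the same way had 6.19% under 0.05 with shrunken and 5.32% with own dispersions. Without control 1 and SH1 1 there were 935, against 870, so part of the excess may come from the selection. In the other 7 libraries all 24 had the same sign, which is no separate test where libraries do not overlap. There 13 transcripts were called, 11 of them among the 24. The count fell to 10 without SH1 2, 13 without control 2, and 15 without control 3, SH3 1 or SH3 3. It was 3 when only the groups compared were fitted and 492 with DESeq2.

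The list of NF-kB and inflammatory genes was higher in SH1 (camera, adjusted p = 0.0042; adjusted p = 0.207 with an estimated correlation; 1.73e-05 to 0.207 over 25 settings). Of 14 measured members 1 rose over all genes in edgeR, CXCL1, and 6 rose adjusted over the list alone; DESeq2 called 1 other, CSF2, and not CXCL1 (adjusted p = 0.498). Members with values that passed over the list alone were LIF, an interleukin 6 family cytokine (1.61 ± 0.41, adjusted p over all genes 0.415), the chemokine CXCL5 (2.07 ± 0.58, 0.516) and SOD2, the mitochondrial superoxide dismutase (1.20 ± 0.32, 0.452). TNFAIP3 entered this list with its other listed transcript. Mesenchymal and invasion genes had an adjusted p of 0.061 in the direction of a fall (adjusted p = 0.393 with an estimated correlation), with 0 of 12 past the threshold over all genes in edgeR and 1 higher and 4 lower adjusted over the list alone; in the other 7 libraries that p was 0.0393 (adjusted p = 0.515 with an estimated correlation). DESeq2 called 4 of the 12 lower, and 6 had an unadjusted p under 0.05 in edgeR. Of 9 epithelial genes 1 fell (KRT19), the same 1 adjusted over the list alone, with an adjusted p of 0.232 for the list. Of 11 immediate early genes 1 rose (EGR1), also adjusted over the list alone (adjusted p = 0.864 for the list, tested as higher, with a mean log2 fold change of 0.67 and a median of -0.69).

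**Figure D1:**
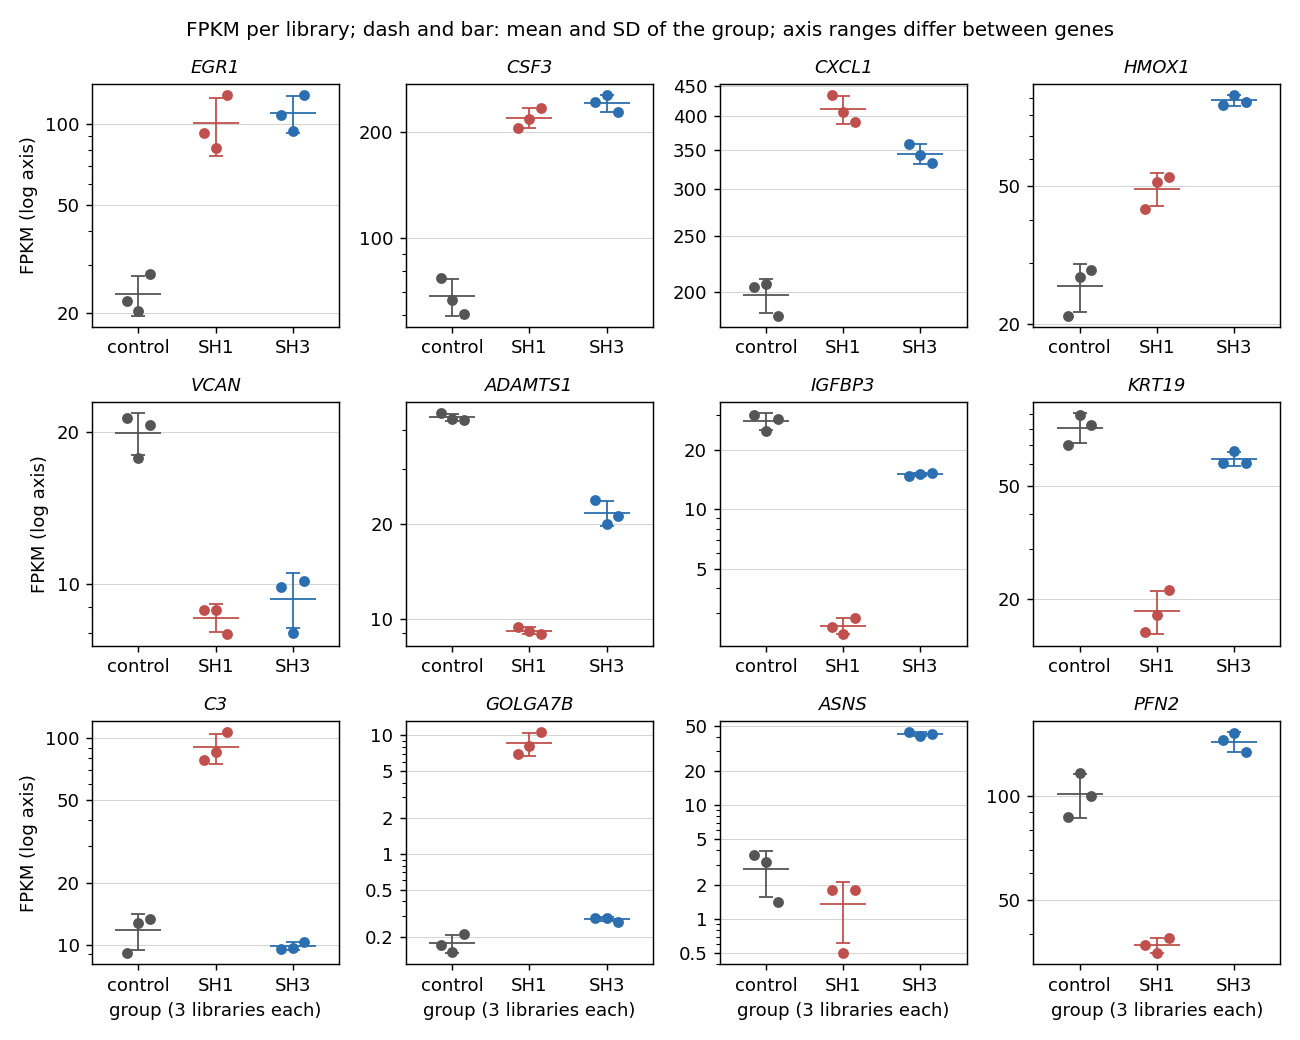
FPKM per library on a log axis (axis ranges differ) of 12 genes chosen after their values were seen, in control, SH1 and SH3; points are libraries, the dash is the mean and the bar the SD (n = 3). CSF3 rises in both knockdown groups, C3 lies at 90.3 in SH1 and 9.84 in SH3, and ASNS at 1.37 in SH1 and 42.3 in SH3.

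In SH3, the same question gave rises alone in the edgeR test of transcripts, though not in DESeq2 or with sums. CSF3 rose from 67.9 ± 8.15 to 243 ± 13.8 FPKM (1.80 ± 0.13, adjusted p = 0.00351) and EGR1 (NM_001964) from 23.4 ± 3.92 to 110 ± 17.1 (2.20 ± 0.21, adjusted p = 0.0117). HMOX1, which encodes the heme-degrading enzyme heme oxygenase (NM_002133), rose from 25.8 ± 4.01 to 88.4 ± 3.03 (1.74 ± 0.21, adjusted p = 0.0468). The transcripts of SYNCRIP and WSB1 that had 0 counts in the controls were at least 759-fold (adjusted p = 0.00672) and at least 357-fold higher (adjusted p = 0.0499).

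These 5 transcripts, 5 higher and 0 lower, passed the edgeR test in SH3. In 5 of 5 the libraries of the groups did not overlap. At an unadjusted p under 0.05 there were 1023, against 875 at a share of 0.05. Simulated unchanged groups selected as the table was had 5.64% under 0.05 with shrunken and 4.21% with own dispersions. In the other 7 libraries there were 1005, against 870. Past the adjusted threshold the other 7 libraries gave 1 (CSF3, adjusted p = 0.04). The count was 12 without control 1, 1 without SH1 1, 2 without control 2 or control 3, and 3 without SH1 2 or SH1 3. It was 0 when edgeR was fitted to these groups alone (487 at an unadjusted p under 0.05), 18 with limma-trend and 358 with DESeq2, of which 183 were higher and 175 lower.

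Of the fixed lists, 4 passed camera in SH3, and 0 of the 4 held with an estimated correlation. Growth factors and their receptors were higher (16 measured, adjusted p = 0.00278; adjusted p = 0.156 with an estimated correlation; 0.00107 to 0.156 over 25 settings), with 0 members past the threshold over all genes in edgeR (2 at an unadjusted p under 0.05), 2 in DESeq2 and 2 adjusted over the list alone. The 2 were in both cases EREG, an EGF receptor ligand (2.86 ± 0.38, adjusted p over all genes in edgeR 0.0608), and MET, the receptor of hepatocyte growth factor (2.72 ± 0.56, 0.375). NF-kB and inflammatory genes were higher (14 measured, adjusted p = 0.00278; adjusted p = 0.156 with an estimated correlation; 0.000197 to 0.156 over 25 settings), with 0 members past it over all genes in edgeR (4 at an unadjusted p under 0.05), 0 in DESeq2 and 2 adjusted over the list alone, CXCL1 (0.76 ± 0.10, 0.0608) and LIF (1.75 ± 0.41). ATF4 targets, which include genes of amino acid synthesis and transport, were higher (17 measured, adjusted p = 0.0336; adjusted p = 0.2 with an estimated correlation; 0.00132 to 0.2 over 25 settings). Over all genes 0 passed in edgeR (2 at an unadjusted p under 0.05) and 1 in DESeq2, and adjusted over the list alone 1 did, in both cases the asparagine synthetase gene ASNS (3.90 ± 0.59, adjusted p over all genes in edgeR 0.109). DNA replication genes were lower (15 measured, 13 with a negative log2 fold change, adjusted p = 0.0424; adjusted p = 0.275 with an estimated correlation), with 0 members past the threshold over all genes in edgeR (0 at an unadjusted p under 0.05), 0 in DESeq2 and 0 adjusted over the list alone. In the other 7 libraries 0 of these 4 lists passed (adjusted p 0.0534, 0.0534, 0.0779 and 0.135). DNA replication genes passed in 12 of 25 settings (0.0132 to 0.275).

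Changes shared by SH1 and SH3 were asked for because both groups carry the same knockdown label. CSF3, EGR1 and the transcripts of SYNCRIP and WSB1 rose in both in edgeR, and 0 fell in both. That makes 4 transcripts, against 0.00372 (higher) and 0 (lower) from the product of the counts. The product treats the comparisons as independent, although both use the same controls, in which the transcripts of SYNCRIP and WSB1 had 0 counts. The highest count in 20 simulations of unchanged groups that shared these controls was 0, which is no support for the 4, since 0 of 66 transcripts truly changed 8-fold in SH1 were recovered in such simulations. Across transcripts, which are not independent, the log2 fold changes of SH1 and SH3 had a Pearson correlation of 0.55 and a covariance of 4.288. Simulated shared controls gave a mean correlation of 0.499 and covariances of 2.733 with shrunken and 0.6614 with own dispersions, so that part of the correlation may come from the shared controls; the covariance lay 1.56 and 3.63 above these. With the other 7 libraries 1 transcript was shared. The shared count was 1 without SH1 1, 2 without control 2 or control 3, 0 in the fits of only the groups compared and 170 with DESeq2 (155 higher and 15 lower). In edgeR 0 transcripts changed in opposite directions.

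Against the average of both knockdown groups 21 transcripts of 20 genes changed, 13 higher and 8 lower. CPA4, a carboxypeptidase gene (NM_016352), fell from 16.4 ± 0.634 to 2.11 ± 0.228 in SH1 and 1.14 ± 0.565 in SH3 (-3.47 ± 0.43, adjusted p = 0.0275). VCAN fell from 19.9 ± 1.88 to 8.56 ± 0.54 and 9.34 ± 1.17 (-1.23 ± 0.14, adjusted p = 0.02). EREG (NM_001432) rose from 1.32 ± 0.295 to 7.45 ± 1.68 and 9.88 ± 0.91 (2.63 ± 0.35, adjusted p = 0.0345), HMOX1 rose by 1.28 ± 0.18 (adjusted p = 0.0433; 0.83 in SH1, adjusted p = 0.35) and CXCL1 by 0.85 ± 0.09 (adjusted p = 0.0114). ADAMTS1 fell (-1.71 ± 0.12; -1.05 in SH3, adjusted p = 0.0622), while EGR1 (2.10 ± 0.19) and CSF3 (1.69 ± 0.12) rose. The average also passed, mostly through SH1, for IGFBP3 (-2.24 ± 0.22, with -0.93 ± 0.26 in SH3, adjusted p = 0.821), KRT19 (-1.33 ± 0.18, with -0.41 ± 0.22, adjusted p = 0.842) and POFUT1 (-0.74 ± 0.10, with -0.36 ± 0.12, adjusted p = 0.821). The same held for C3 (1.27 ± 0.16, with -0.29 ± 0.18 in SH3, adjusted p = 1), GOLGA7B (3.06 ± 0.41, with 0.63 ± 0.41 in SH3, adjusted p = 1) and both transcripts of L1CAM (1.36 and 1.96, with 0.60 and 0.99 in SH3, adjusted p = 0.821 and 0.705). The transcripts of SYNCRIP, TNFAIP3, UBR4 and WSB1 with 0 counts in the controls were at least 630-fold, 286-fold, 244-fold and 269-fold higher. Those of GPR176 and LRRC8A passed as lower in the average through their 0 counts in SH1. In SH3 against control they had -1.72 ± 0.77 (adjusted p = 0.821) and 0.87 ± 0.64 (adjusted p = 1), and the sum of the listed LRRC8A transcripts had 0.33 in the average.

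In 18 of the 21 transcripts the 6 knockdown libraries did not overlap with the controls. Chance gives that for 2.38% of transcripts not chosen by their p, a share that also ignores the selection of the table. At an unadjusted p under 0.05 there were 1293 transcripts in this average, against 875 at a share of 0.05, which ignores the selection of the table. Simulated unchanged groups selected the same way had 6.81% under 0.05 with shrunken and 5.37% with own dispersions. In the other 7 libraries there were 962, against 870, so part of the excess may come from the selection. Past the adjusted threshold the other 7 libraries gave 2. The count was 21 without control 1, 3 without control 2, 6 without control 3, SH1 1 or SH1 2, and 7 without SH1 3 or any 1 library of SH3. It was 7 when the knockdown libraries were fitted as 1 group and 459 with DESeq2. NF-kB and inflammatory genes were higher (camera, adjusted p = 0.00114; adjusted p = 0.143 with an estimated correlation; 4.23e-06 to 0.143 over 25 settings), with 1 of 14 past the threshold over all genes in edgeR (CXCL1), 1 in DESeq2 (CSF2) and 4 adjusted over the list alone. Growth factors and receptors were higher as well (adjusted p = 0.0371; adjusted p = 0.334 with an estimated correlation; past it in 13 of 25 settings), with 1 of 16 past it in edgeR (EREG), 2 in DESeq2 (EREG and MET) and 2 adjusted over the list alone.

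The direct comparison of SH3 with SH1 asks where the knockdown groups differ. ASNS (NM_001673) was at 42.3 ± 1.56 FPKM in SH3 and 1.37 ± 0.751 in SH1, with 2.74 ± 1.18 in control (5.01 ± 0.63, adjusted p = 0.0283). C3 was lower in SH3, at 9.84 ± 0.409 FPKM, than in SH1 (-3.13 ± 0.19, adjusted p = 0.000962), and so were GOLGA7B (-4.85 ± 0.47), MYOF (-3.83 ± 0.35) and both transcripts of L1CAM (-1.51 ± 0.19 and -1.95 ± 0.25). IGFBP3 (2.63 ± 0.28), ESM1, an endothelial proteoglycan gene (2.08 ± 0.27), PFN2 (2.02 ± 0.16), RPS24 (1.91 ± 0.19), KRT19 (1.85 ± 0.22) and ADAMTS1 (1.32 ± 0.15) were higher in SH3. Both listed copies of the same SLC16A1 transcript, a monocarboxylate transporter, were higher by 1.64 ± 0.21. The transcripts of LRRC8A and GPR176 with 0 counts in SH1 were at least 921-fold and 218-fold higher in SH3, and a copy of a PPP1R11 transcript with 0 counts in SH3 was at least 412-fold lower.

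These were 17 transcripts of 15 genes, 11 higher and 6 lower in SH3, with adjusted p up to 0.0472 (GPR176). In 17 of 17 the libraries of the groups did not overlap. At an unadjusted p under 0.05 there were 1094, against 875 at a share of 0.05. Simulated unchanged groups selected as the table was had 5.65% under 0.05 with shrunken and 4.19% with own dispersions. Without control 1 and SH1 1 there were 1009, against 870. In the other 7 libraries 5 were called, all among the 17. The count was 23 without control 1, 2 without SH1 2, 3 without SH1 1, 4 without SH1 3 or SH3 1, 5 without SH3 3, 7 without control 2 and 10 without control 3 or SH3 2. It was 4 when only the groups compared were fitted and 406 with DESeq2, of which 217 were higher and 189 lower.

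ATF4 targets were higher in SH3 than in SH1 (camera, adjusted p = 2.33e-05; adjusted p = 0.055 with an estimated correlation; past the threshold in 24 of 25 settings). Of 17 members 13 had a positive log2 fold change, 1 rose over all genes and 1 adjusted over the list alone, ASNS in both. Next by p were DDIT3, a transcription factor of the stress response (2.40 ± 0.82, adjusted p over all genes 0.766), and the amino acid transporter genes SLC7A5 (3.06 ± 1.58) and SLC38A2 (1.44 ± 0.76). Against control, SLC7A5 had -3.49 in SH1 and -0.435 in SH3, so that its difference is no rise in SH3. The values in SH1 and SH3 were -1.12 and 3.90 for ASNS, -1.04 and 1.36 for DDIT3, and -0.266 and 1.17 for SLC38A2. As in SLC7A5, the larger value was the negative one in SH1 for PSAT1 (-2.97 and 0.259) and SHMT2 (-3.18 and 0.521). For ATF3 (-0.688 and 3.28) it was the positive one in SH3. The difference of the list is therefore not a rise in SH3 alone. In the other 7 libraries the list had an adjusted p of 0.000537.

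Genes of PI3K, AKT and mTOR signalling, which the study names, did not pass the edgeR test. These are RNA levels, which measure neither the activity of the pathway nor the output of ribosomal RNA. In simulations this test recovered 0 of 66 transcripts changed 8-fold in SH1, so a missing call is no sign of an unchanged gene. Of the 31 components in the list, 19 were measured. Of the 19 measured components 0 passed in SH1, in SH3 or in their average (2, 1 and 1 at an unadjusted p under 0.05), and the list had adjusted p of 0.33, 0.612 and 0.46. Adjusted over the list alone 1 component was higher in SH1 and 0 in SH3. It was RICTOR, of whose 5 listed transcripts the one entered (NM_001285439) had 0 counts in every control library. DESeq2 called this transcript in SH1 (adjusted p = 1.57e-05; up to 0.917 over its settings), in SH3 (0.0011) and in the average (2.25e-05), whereas the 5 transcripts summed had a log2 fold change of 0.50 ± 0.51 in SH1 (edgeR, adjusted p = 0.917). Of 10 inhibitors of the pathway 0 passed over all genes in edgeR (1 at an unadjusted p under 0.05 in SH1 and 0 in SH3), 0 in DESeq2 and 0 adjusted over the list alone (adjusted p for the list 0.917 in SH1, tested as higher with a median log2 fold change of -0.22 and a mean of -0.07, and 0.195 in SH3). MTOR (0.20 ± 0.41 in SH1, 0.36 ± 0.41 in SH3) and TSC2 (-0.97 ± 0.71 and -1.33 ± 0.72) did not pass in edgeR, nor did MYC, at 3.83 ± 0.325 FPKM in control, 1.8 ± 0.451 in SH1 and 3.49 ± 0.581 in SH3 (-1.19 ± 0.50 and -0.17 ± 0.50). DESeq2 on sums called MYC in SH1 (-1.22, adjusted p = 0.000778; up to 1 over its settings) and TSC1 in SH3 (-1.80, adjusted p = 0.0331). The errors of AKT1 (1.08 ± 2.44 in SH1), AKT2 (1.72 ± 2.0), PIK3CA (0.87 ± 2.99), PIK3R1 (3.16 ± 2.37), RPS6KB1 (1.26 ± 2.73) and TSC1 (0.00 ± 1.40) were too wide for a statement. Of 14 measured ribosome biogenesis genes 0 passed over all genes in edgeR (1 at an unadjusted p under 0.05 in SH1 and 1 in SH3) and 0 adjusted over the list alone, with adjusted p for the list of 0.232 in SH1 and 0.195 in SH3. DESeq2 called GAR1 lower in SH1. Of 10 genes of RNA polymerase I and SL1 0 passed over all genes in edgeR, 0 at an unadjusted p under 0.05, 0 in DESeq2 and 0 adjusted over the list alone (0.621 and 0.905 for the list).

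**Figure D2:**
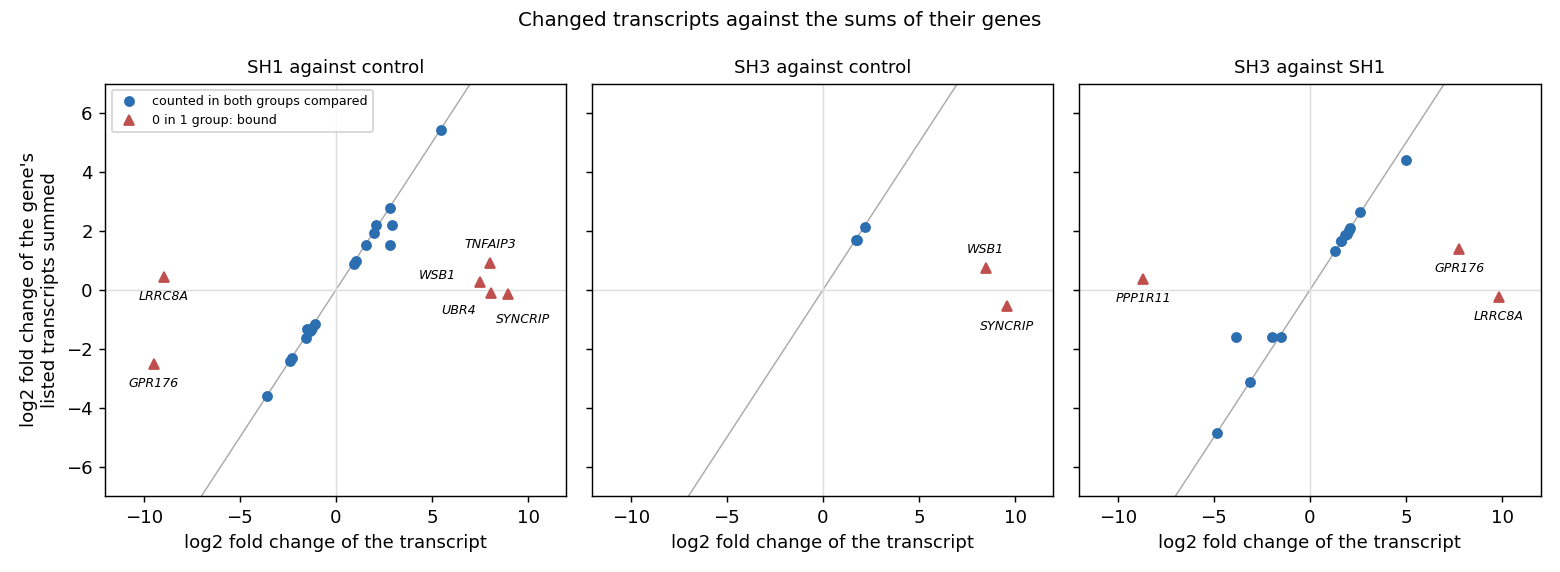
Log2 fold change of each changed transcript (x axis) against that of the sum of the listed transcripts of its gene (y axis) in SH1 against control, SH3 against control and SH3 against SH1; triangles are bounds for transcripts at 0 in a whole group, and the diagonal marks equal values. Most transcripts counted in both groups lie near the diagonal, many as the only listed transcript of their gene, while MYOF lies off it (-3.83 and -1.59 in SH3 against SH1); the sums of those at 0 in a group lie far inside their bounds, GPR176 at -2.50 in SH1 being the farthest from 0.

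Some values rest on reads that cannot be placed with certainty. The copies of SLC16A1 and PPP1R11 share their sequence, both L1CAM transcripts share exons, and RPS24 has processed copies in the genome. Called transcripts without a group at 0, of genes with more than 1 listed transcript, also passed as sums: 6 of 6 in SH1, 1 of 1 in SH3, 7 of 7 in SH3 against SH1 and 4 of 4 in the average. Where L1CAM and SLC16A1 were called, their sums consist of called transcripts alone, so that these passes are no separate test. For 12, 2, 7 and 11 others the sum is the transcript itself. Of those at 0 in a group 0 of 6, 0 of 2, 0 of 3 and 0 of 6 passed as sums in edgeR.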

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

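Chosen only after the results were seen were the tests on sums of transcripts (reads assigned to another transcript, a change of the whole gene), on the distance between opposite calls and on genes with 1 annotated transcript.

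In 17 transcripts the effect of SH3 differed from that of SH1 in the edgeR test of the difference itself, given as log2 of SH3 over SH1. ASNS differed by 5.01, with -1.12 ± 0.54 in SH1 (adjusted p = 0.645) and 3.90 ± 0.59 in SH3 (adjusted p = 0.109), each against control and not past the threshold alone. ESM1 differed by 2.08 (-1.26 in SH1 and 0.83 in SH3) and SLC16A1 by 1.64 in both of its copies (-1.32 in SH1, adjusted p = 0.0576, and 0.32 in SH3). Genes that fell in SH1 and differed upward were IGFBP3 (2.63; -3.56 in SH1 and -0.93 in SH3), PFN2 (2.02; -1.56 and 0.46), RPS24 (1.91; -1.36 and 0.54), KRT19 (1.85; -2.26 and -0.41) and ADAMTS1 (1.32; -2.37 and -1.05 ± 0.15, adjusted p = 0.0622 in SH3). Genes that rose in SH1 and differed downward were GOLGA7B (-4.85; 5.48 and 0.63), MYOF (-3.83; 2.83 and -1.0), C3 (-3.13; 2.84 and -0.29) and L1CAM (-1.51 and -1.95 in its listed transcripts). The fitted differences of LRRC8A (12.8), GPR176 (10.7) and PPP1R11 (-11.7), each at 0 in 1 group, depend on the prior count and are no bounds.

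Library size and scaling, as 1 wrong factor per library, would give every transcript the same difference. The smallest called differences were 1.32 upward (ADAMTS1) and -1.51 downward (L1CAM), a distance of 2.82 ± 0.24 (SE) that no factor changes. Calls in opposite directions make this distance large by construction, so it is no separate test. With other scalings 13 (DESeq2 size factors) to 17 (library totals) of the 17 were still called in the same direction, which argues against scaling as the whole cause. Reads split between transcripts of a gene should give no difference in genes with 1 annotated and 1 listed transcript. In a fit of these genes alone 34 of 118 differed (20 higher, 14 lower), which argues against it as the whole cause for them. Annotated transcripts were counted in the human RefSeq table, and the annotation behind the deposited counts is not known. Both can differ, as AKT2 had 5 listed and 4 annotated transcripts. A batch shared by the libraries of a group cannot be told apart from the group, because 0 of 10 label fields differ between libraries of a group. Different hairpins, different cell lines made with them, or different degrees of knockdown may each be the source, and all were untested since TAF1D was not analysed here.

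In 7 genes (GPR176, LRRC8A, PPP1R11, SYNCRIP, TNFAIP3, UBR4, WSB1) a called transcript had 0 counts in every library of a group. A change of that size alike in all listed transcripts is excluded: the median absolute log2 fold change was 11.7 for these transcripts as fitted and 0.555 for the sums. The fitted value depends on the prior count, and transcripts outside the table are not in the sums. A smaller change of the whole gene stays open, above all for GPR176, whose sum had -2.50 in SH1. A candidate explanation is reads of a gene assigned to another transcript, for which the sums should lose the call. Of the 7, 0 passed as sums in edgeR (lowest adjusted p 0.0504, GPR176). Other called transcripts of genes with more than 1 listed transcript passed in 6 of 6 in SH1, 1 of 1 in SH3 and 7 of 7 in SH3 against SH1. That contrast is no separate test, since it includes both L1CAM transcripts and both SLC16A1 copies, whose sums consist of called transcripts. A switch between transcripts in the cells also predicts that sums lose the call, and cannot be told apart from reads assigned to another transcript. The other listed transcripts were higher in the group at 0 in 6 of the 7 genes, GPR176 being the exception.

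Changes in SH1 could stem from the selection of the table on control 1 and SH1 1. If that were their source, transcripts called in the other 7 libraries would match the direction of the selecting pair about as often as not. Of these, 13 of 13 matched (100%, exact 95% binomial lower bound 75.3%). They are transcripts of 12 genes and were called without the selecting pair, 11 of them among the 24. The match therefore cannot decide on those of the 24 that were called only with that pair. As sums 49 of 57 matched (86%, lower bound 74.2%), which falls just short of the limit of 75%. The transcripts pass that limit only with transcripts of the same gene counted as independent. Whether selection gives as many false calls in unchanged groups cannot be told: 0 of 20 simulations of each kind reached the observed 24, but these called 0 transcripts, and 0 of 66 truly changed 8-fold in SH1 were recovered in such simulations. A shared batch of the SH1 libraries stays open, as does an effect of the hairpin on other genes than TAF1D, which was not tested.

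Other splits of the same libraries were counted for each number of changed transcripts. For SH1 against control (24 real, highest other 1), SH3 against control (5 and 0) and SH3 against SH1 (17 and 1), 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. With the knockdown libraries fitted as 1 group of 6, 2 of 84 splits gave at least the real 7, a share under 0.05. The other gave 22, from the SH1 libraries against the remaining 6, which points to a structure of the samples. Because the table was selected on control 1 and SH1 1, the splits are not equivalent, and this share does not exclude chance. For changes shared by SH1 and SH3, 1 of 100 splits gave the real 4 (highest other 2), a share under 0.05 for a count of 4 alone. That count includes the transcripts of SYNCRIP and WSB1 at 0 in the controls, whose sums did not pass in edgeR. Without them CSF3 and EGR1 are left, a number that other splits reached, so chance is not excluded for these. Without SH1 1 the count was 1, which 8 other splits reached. For gene lists, 2 of 10 splits gave as many in SH1 (1 real, highest other 1), 1 of 10 in SH3 (4 and 0) and 2 of 10 in SH3 against SH1 (1 and 2), again too few splits. For the averaged comparison, with the knockdown libraries as 1 group, 3 of 84 did (2 real, highest other 2). That is a share under 0.05 for a count of 2 alone, and for the same reason it does not exclude chance. With separate knockdown groups that count was 1 without control 2, control 3, SH1 1, SH3 1 or SH3 3, 4 without SH1 2, and 0 with an estimated correlation, and 18 other splits gave at least 1 list.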

How the results depend on the processing

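Chosen only after the data were seen were the settings with the other 7 libraries, with sums, with genes of 1 annotated transcript, with the authors' factors, with totals from count over FPKM, without robust dispersions, and with DESeq2 or limma-voom on sums; the rest were planned. Counts of changed transcripts are given for the averaged comparison, SH1, SH3, SH3 against SH1 and shared changes, in that order. The cause of a change was not tested unless stated.

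The counts (21, 24, 5, 17 and 4) stayed within 1.5 times with DESeq2 size factors, without a filter, with a minimum log2 fold change of 1, with the authors' factors and with totals from count over FPKM. In SH3 against control 3 were left with library totals only and 3 with the stricter filter, the others staying within that range. DESeq2 gave 459, 492, 358, 406 and 170. Limma-trend gave 42, 85 (55 higher, 30 lower), 18 (14 and 4), 67 (34 and 33) and 12 (10 and 2). Fits of only the groups compared, with fewer libraries for the spread, gave 7 (6 and 1), 3 (2 and 1), 0, 4 (2 and 2) and 0; the 0 in SH3 stood beside 487 at an unadjusted p under 0.05, and DESeq2 gave 358. Without robust dispersions 7 were left in the average, 3 in SH3 and 8 (4 and 4) in SH3 against SH1; in SH1 18 were left (12 and 6).

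The other 7 libraries, fewer samples by construction, gave 2 (1 and 1), 13, 1, 5 (2 and 3) and 1. Leaving out 1 library gave 3 (without control 2) to 21 (without control 1), 10 (without SH1 2) to 20 (without control 1), 1 (without SH1 1) to 12 (without control 1), 2 (without SH1 2) to 23 (without control 1) and 1 (without SH1 1) to 6 (without control 1). Sums gave 71, 137, 26 (19 and 7), 87 and 18 (12 and 6), and in the other 7 libraries 21 (9 and 12), 57, 7 (6 and 1), 57 and 5 (4 and 1). DESeq2 on sums gave 360, 461, 258 (132 and 126), 406 (209 and 197) and 122 (83 and 39), and limma-voom 68 (30 and 38), 145, 31 (20 and 11), 96 (50 and 46) and 20 (10 and 10). Genes with 1 annotated and 1 listed transcript, far fewer tests, gave 18 (11 and 7) in SH3, 34 in SH3 against SH1 and 10 (6 and 4) shared.

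Nothing says that equal numbers pair samples, and residuals gave no sign of it: those of libraries with the same number correlated by -0.276 to 0.0324 and 0 of 9 such pairs exceeded 0.1. The -0.276 belongs to control 1 and SH1 1, the pair on which the table was selected. The check is distorted by that selection and cannot exclude a pairing of control with SH1. The replicate block gave 7 (6 and 1), 16, 2, 5 (2 and 3) and 2, and 1 list in place of 2 in the average.

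Lists past the threshold numbered 2, 1, 4 and 1 (averaged, SH1, SH3, SH3 against SH1). With an estimated correlation 0, 0, 0 and 0 passed, against 7, 4, 7 and 5 at an unadjusted p under 0.05 with camera's preset correlation. Fry, which tests a list alone and not against other genes, gave 4, 7 (3 up, 4 down), 4 and 2 (1 and 1); ranks gave 0, 0, 3 and 1. In the average 1 passed with limma-trend, in the other 7 libraries, with sums and with sums in the other 7 libraries. In SH1 2 (1 up, 1 down) and 4 (2 and 2) passed in the other 7 libraries, without and with sums, and in SH3 0 did without sums. Leaving out 1 library gave 1 (without control 2, control 3, SH1 1, SH3 1 or SH3 3) to 4 (without SH1 2) in the average. In SH1 it gave 1 to 3 (without SH3 1), with 2 without control 1, and in SH3 2 (without control 1, control 2 or SH3 2) to 4. In SH3 DESeq2 size factors, no filter and limma-trend gave 3 up and 0 down, the fit of only the groups compared 3 up and 2 down, and sums 4 up and 0 down. The lists past the threshold kept their direction in all 25 settings.

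Of the values of named genes 36 reversed, 591 fell below the threshold, 7 passed it and 2147 kept direction and side. All 36 are transcripts at 0 in a group, set beside sums of the gene. Their log2 fold changes follow as sums, as sums in the other 7 libraries, and with DESeq2 and limma-voom on sums. SYNCRIP in both averaged was -0.344, -0.225, -0.33 and -0.334, LRRC8A in both averaged 0.333, 0.164, 0.35 and 0.311, and UBR4 in both averaged -0.114, -0.153, -0.0955 and -0.103. SYNCRIP in SH1 against control was -0.133, -0.0385, -0.113 and -0.126, LRRC8A in SH1 against control 0.446, 0.181, 0.469 and 0.396, and UBR4 in SH1 against control -0.0975, -0.0626, -0.0723 and -0.0909. SYNCRIP in SH3 against control was -0.555, -0.411, -0.547 and -0.543. LRRC8A in SH3 against SH1 was -0.226, -0.0346, -0.238 and -0.17, and PPP1R11 in SH3 against SH1 0.376, 0.292, 0.363 and 0.375.

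Totals from count over FPKM moved the median log2 fold change in SH1 from 0.044 to 0.153. DESeq2 gave no adjusted p for 1370, 1707, 1707 and 2375 transcripts. The alternative pseudocount was not run because the table holds counts. No setting varied the depth, so what it limits is not known; in each library 3417 to 3882 transcripts had a count of at least 100. In simulations with the measured means and spread at most 6 of 66 transcripts and 42 of 66 sums changed 8-fold were recovered, where the common coefficient of variation between libraries was 1.63 for transcripts and 0.948 for sums.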

Other observations

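Sums of the listed transcripts of a gene and their tests were chosen after the data were seen, as was the choice of the genes named here. As sums (6393 genes tested, FPKM summed as well; transcripts outside the table are not counted), 18 genes changed the same way in SH1 and SH3, 12 higher and 6 lower, and ASNS changed in opposite directions. GDA, the guanine deaminase gene, rose from 0.383 ± 0.15 FPKM in control to 12.2 ± 1.64 in SH1 and 5.25 ± 0.629 in SH3 (SD, n = 3; averaged log2 fold change 4.12 ± 0.26 (SE), adjusted p = 0.000288). HES1, a Notch target, rose from 11.8 ± 2.49 to 48.4 ± 18.7 and 47.8 ± 3.13 (1.92 ± 0.26, adjusted p = 0.0164), and the cyclin-dependent kinase inhibitor CDKN1A from 5.83 ± 0.324 to 14.6 ± 2.21 and 17.5 ± 0.971 (1.34 ± 0.16, adjusted p = 0.00986). SEL1L3 (2.43 ± 0.27), EREG (2.59 ± 0.21), the potassium channel gene KCNK3 (1.62 ± 0.18) and GRB10, an adaptor of insulin receptor signalling (1.59 ± 0.22), rose as well. CPA4 fell from 16.5 ± 0.627 to 2.86 ± 0.191 and 1.5 ± 0.113 (-3.13 ± 0.15, adjusted p = 8.28e-05) and FST, which encodes the activin-binding follistatin, from 23.9 ± 3.55 to 8.99 ± 1.9 and 9.98 ± 1.28 (-1.45 ± 0.17, adjusted p = 0.00733). In the other 7 libraries the averaged change did not pass in edgeR for HES1 (adjusted p = 0.088), GRB10 (0.088), CDKN1A (0.0502) and FST (0.0502). It passed for GDA, SEL1L3, EREG, KCNK3 and CPA4. ASNS fell in SH1 from 11.6 ± 1 to 5.35 ± 0.816 (-1.26 ± 0.13, adjusted p = 0.00283) and rose in SH3 to 117 ± 6.87 (3.16 ± 0.14, adjusted p = 0.000105).

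In SH1 the sums of EDN1, the endothelin gene (5 ± 1.16 FPKM in control and 0.737 ± 0.237 in SH1; SD, n = 3; -2.91 ± 0.38 (SE), adjusted p = 0.00785), RGS4 (-3.04 ± 0.28, adjusted p = 0.00195) and SERINC2 (-3.29 ± 0.36, adjusted p = 0.00311) fell, and INAVA rose from 0.623 ± 0.0651 to 8.13 ± 0.748 (3.55 ± 0.32, adjusted p = 0.00181). Larger changes in SH1 rest on counts at or near 0, which sums do not remove. ARPC2, with 0 counts in every control library and 1 of 4 annotated transcripts listed, was at least 91.9-fold higher (adjusted p = 0.0385). INTS3 fell (-9.15 ± 0.89, adjusted p = 0.00227), with counts of 0, 2 and 0 in SH1. In SH3 MET rose from 1.04 ± 0.171 to 4.81 ± 0.987 (2.34 ± 0.29, adjusted p = 0.0189). In the other 7 libraries EDN1 (edgeR, adjusted p = 0.0518), ARPC2 (0.14) and MET (0.0885) did not pass, while RGS4, SERINC2, INAVA and INTS3 did. NF-kB and inflammatory genes were higher in SH1 as sums (camera, adjusted p = 1.73e-05; adjusted p = 0.0566 with an estimated correlation). Of 13 members 4 rose over all genes and 8 adjusted over the list alone, among them the cytokine gene CSF2 (2.37 ± 0.34, adjusted p = 0.0129), CXCL5 (2.03 ± 0.34, adjusted p = 0.0234) and SOD2 (1.08 ± 0.20, adjusted p = 0.0405). Averaged over both knockdown groups, the list passed as well (adjusted p = 4.23e-06; adjusted p = 0.0435 with an estimated correlation). ATF4 targets were higher in SH3 than in SH1 (adjusted p = 3.96e-06; adjusted p = 0.0393 with an estimated correlation), with 2 of 17 past the threshold over all genes, ASNS (4.42 ± 0.15) and PSPH of serine synthesis (1.66 ± 0.14, adjusted p = 0.00118), and 3 adjusted over the list alone. Of 12 mesenchymal and invasion genes TGFBI (-2.32 ± 0.22), TAGLN (-1.81 ± 0.27) and LOX (-1.15 ± 0.17) fell in SH1 and TNC rose (1.60 ± 0.22), 1 higher and 3 lower also adjusted over the list alone (adjusted p = 0.0622 for the list).

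Correlations between libraries across transcripts, which are not independent, were low: Spearman's rho was 0.338 to 0.461 within groups and -0.0299 to 0.434 between groups. The -0.0299 belongs to control 1 and SH1 1, on which the table was selected, and all other pairs between groups had at least 0.301. The first principal component (20.8% of the variance) placed control 1 at -256 and SH1 1 at 238, with the other 7 libraries between -22.1 and 45.5. The selection sets this pair apart by construction, so its distance shows neither sample quality nor biology. The common biological coefficient of variation in edgeR was 1.63 for transcripts and 0.948 for sums.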
